A study of Gallus gallus with 12 samples.

How the data were processed

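The samples were 12 RNA sequencing libraries from 6 chick (Gallus gallus) embryos, a node and a lateral library from each. Per the labels, total RNA of 1 to 7 ng was extracted with miRNeasy columns and libraries were made with the SMARTer low RNA kit, which amplifies full-length cDNA. Such small inputs and amplification can leave transcripts out of single libraries at random and repeat others, so p values rest on the spread between embryos, and counting intervals or floors cover counting error only. Per the submitters' processing notes Bowtie2 2.2.3 was used, with no role stated. The counter, the annotation release, the genome build and the use of strand are not given in the sources used here, so reads of near-identical copies, of overlapping genes and of antisense partners cannot be told apart. Examples are tubulins, ribosomal proteins and the paired Z and W genes.

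The authors deposited read counts per Ensembl gene, 1 column per library, for 13106 genes with at least 1 count in some library. The authors also deposited a normalized signal table, in which each count is divided by a single size factor per library. These factors equal median-of-ratios factors computed from the counts, with a largest deviation of 0.0%. The counts were the basis of every test, and the normalized values entered only an alternative test. The authors' symbols named 11420 genes, and 621 of the other 1686 were named by accession through a RefSeq gene table that was used for names only. No row lacked a gene. Total counts ran from 18568123 to 30997461 per library. At similar depth, LCM libraries held more genes at 0 (4658 ± 1187, SD, n = 6) than manual libraries (3594 ± 1249). Manual embryo 1 had 2485 and 1609, and the other manual libraries 4123 to 4728, inside the LCM range of 3095 to 5871. Manual embryo 1 thus makes up much of the gap in means, but not all of the difference. LCM node 1, lateral 1 and lateral 2, at 5516, 5871 and 5729, lay above every manual library. The libraries of LCM embryo 3, at 3843 and 3896, lay below those of manual embryos 2 and 3. The lowest LCM value, 3095, is that of the node library of embryo 2, which held the carried reads described below. Subtracting the carried share there lowers the genes detected from 10011 to 8179. An absent count in a single library limits what a fold change can show.

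Groups were taken from the labels, which name the embryo, the dissection method, the cell population and the stage of each library. Replicates are separate embryos. The node and lateral library of an embryo were treated as a pair because the labels name the same embryo. As a check of the pairing, deviations from the group means were correlated between paired libraries, with values of 0.473, 0.116 and 0.215 for manual embryos 1 to 3 and 0.07, 0.03 and 0.067 for LCM embryos 1 to 3. Each of these lay above that embryo's highest correlation with another embryo (-0.148, 0.086, 0.086, -0.021, 0.001 and 0.001). Log2 CPM of tested genes correlated at 0.67 to 0.872 between libraries of an embryo and at 0.648 to 0.756 between embryos of a group.

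Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15) and Benjamini-Hochberg adjustment, with calls at an adjusted p below 0.05. The model held the embryo as a block and the population. A model with a population term for each dissection method gave the effect in manual embryos, the effect in LCM embryos and their difference, on a shared estimate of the spread. Laser capture against manual dissection was tested on counts summed over the libraries of each embryo, 3 sums per method, and this comparison holds different embryos as well as different methods. Fold changes are on the log2 scale with standard errors. Differences per embryo are of log2 CPM with a prior count of 2.

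A total of 31 gene lists (tissues, pathways, cell cycle, metabolism, signs of handling) was tested with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over the lists, for lists with at least 5 tested members. Camera was repeated with an estimated correlation, with which no call held in any comparison. The fry test for movement of a list in a single direction called 0 lists, and fry for change in either direction called 11 lists for node against lateral in both methods, 6 in LCM embryos and 22 for laser capture against manual dissection. Lists share members, such as TBXT in 3 of them. For lists the count of genes is given over all genes and adjusted over the list alone. The agreement of the methods was measured as the correlation of log2 fold changes with each method fitted on its own libraries.

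The genes to name were to be those past the threshold, with the same sign in all embryos concerned, an average log2 CPM of at least 3 (5 for laser capture against manual dissection), and the largest fold changes, plus up to 4 members of each list. This rule, the lists, the tests and most alternatives were set before the data were examined. The rule named only GPR126, so the genes with the smallest unadjusted p that met its other conditions were added after seeing the data. SHH, CHRD, TBXT and GNOT1 were looked up in every library as a check of the labels.

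The methods were tested on simulated counts with the fitted means and dispersions of the real genes, in which 200 genes were changed. The changed genes and the list members were drawn from genes with an average log2 CPM of at least 3. Loss of transcripts from single libraries was not simulated apart from the fitted dispersions. The rates below therefore do not cover genes of lower counts. For node against lateral in both methods edgeR called 24 of 100 genes changed 4-fold and 61 of 100 changed 16-fold, with 5 false calls, and DESeq2 1.42.0 called 48 and 82 with 163 false calls. For laser capture against manual dissection edgeR called 8 and 63 with 2 false calls, and DESeq2 24 and 84 with 120. For manual embryos alone edgeR called 6 and 39, for LCM embryos 8 and 34, and for the difference of the methods 3 and 26. A list of 20 genes shifted 4-fold was called in all 5 comparisons with the preset correlation and in 3 with an estimated correlation, and 0 unshifted lists were called. It was not called with an estimated correlation for LCM embryos alone or for the difference of the methods. Fitted means and dispersions are set per gene, so these simulated lists hold no correlation between their genes. In the real lists the estimated correlation ran from -0.089 (surface ectoderm) to 0.837 (W chromosome genes) for node against lateral in both methods. The 0 calls of unshifted lists therefore do not cover lists of correlated genes.

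Alternatives were median-of-ratios size factors, no filter on low counts, a minimum CPM of 5 in 3 libraries, DESeq2, limma voom with sample quality weights, no embryo block, each embryo left out, the method fitted alone, the mean of both method effects, embryos of 9 somites only, limma on log2 of the normalized values with a pseudocount of 1, and removal of mitochondrial and ribosomal protein genes. For laser capture against manual dissection they also included single libraries with a population term, node libraries alone and lateral libraries alone. A robust estimate of the spread, genes counted in all 12 libraries, and subtraction of a carried share of counts in the LCM node library of embryo 2 were chosen after seeing the data. That share was estimated as 3.45% of the manual lateral library of embryo 1, from 104 genes counted at 100 or more there. Outside that embryo these genes were counted in no library other than the LCM node library of embryo 2. Tables and plots were made with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Checks of gene length and GC content were not made, because no genome was used here.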

Results

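RNA was profiled from the mature Organiser of chick embryos, the node at the posterior end of the axis that lies within the tissue elongating the trunk. From each of 6 embryos there were 2 libraries. The node library held fluorescent cells that had stayed in the Organiser since its cells were marked as gastrulation ended, and the lateral library held ectoderm and mesoderm beside it. Tissue from 3 embryos was dissected by hand while live, and tissue from the other 3 was cut by laser capture microdissection (LCM) from paraffin sections of embryos fixed in modified methacarn. Embryo 1 of each method had 8 somites and the others had 9. The table held 13106 genes. Total counts per library ran from 18568123 to 30997461 for manual dissection and from 21139477 to 25972879 for LCM. The number of genes with at least 1 count was 9512 ± 1249 in manual libraries and 8448 ± 1187 in LCM libraries (SD, n = 6 each). The median gene had 166.5 counts in the manual lateral library of embryo 1 and 1 count in the LCM lateral library of embryo 1. Only 4909 genes (37.5%) were counted in all 12 libraries.

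**Figure D1:**
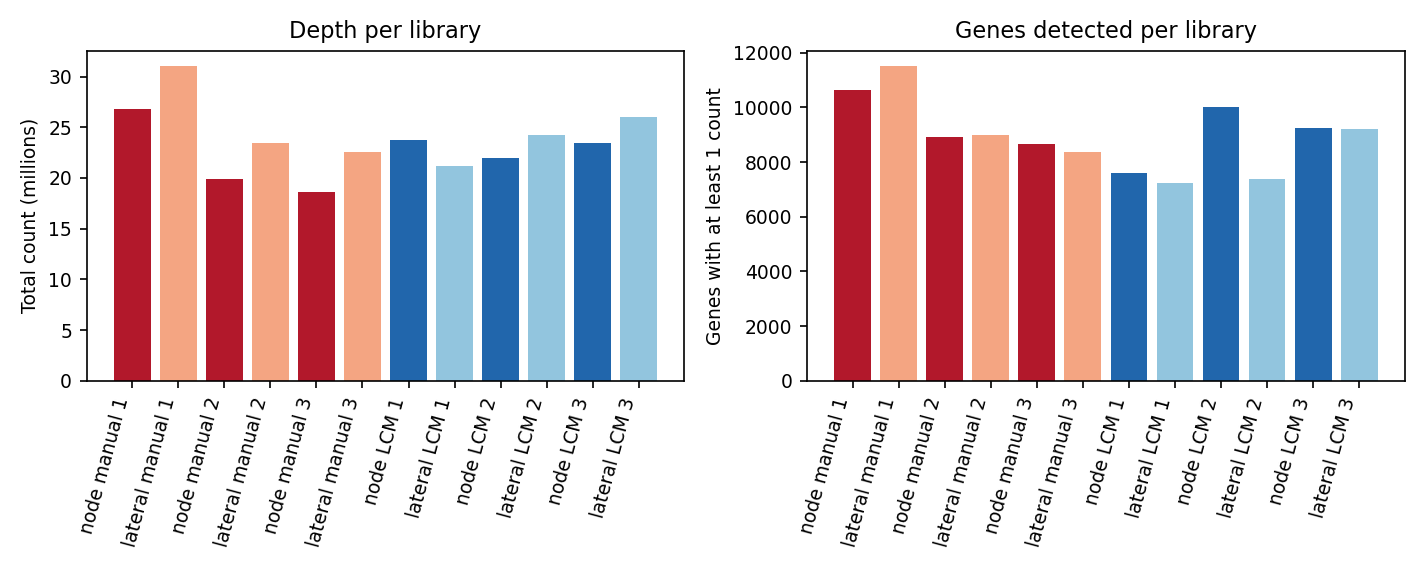
Total count (left) and number of genes with at least 1 count (right) for each of the 12 libraries, as bars coloured by tissue and dissection method. Totals lie between 18568123 and 30997461, and genes detected between 7235 in LCM lateral 1 and 11497 in manual lateral 1.

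Known Organiser genes were looked up in every library as a check of the labels. TBXT, the T-box transcription factor of the notochord and primitive streak, had more counts in the node library of all 6 embryos. Its node and lateral counts were 8349 and 1753, 16077 and 526, and 7507 and 3495 in manual embryos 1 to 3, and 35422 and 18038, 17999 and 3924, and 26284 and 10982 in LCM embryos 1 to 3. CHRD, which encodes the BMP antagonist chordin, had 186, 39 and 16 counts in the manual node libraries against 10, 0 and 0 in the lateral libraries. In LCM embryos CHRD had 0, 78 and 543 node counts against 1, 0 and 0 lateral counts, so embryo LCM 1 gave no CHRD signal in node tissue. SHH, the Hedgehog ligand of node and notochord, had 57, 7 and 38 counts in manual node libraries, 2, 0 and 0 in manual lateral libraries, and 0 in all 6 LCM libraries, which allows up to 3 counts in each, for counting error only. GNOT1, a notochord homeobox gene, had 2734 and 368, 1557 and 548, and 1878 and 1696 node and lateral counts in manual embryos 1 to 3. In LCM embryos GNOT1 had 333 and 1251, 810 and 882, and 4581 and 2682, so node counts were lower in LCM embryos 1 and 2, with a difference of -2.29 log2 CPM in embryo 1 and 0.54 in embryo 2 once scaled. Its log2 fold change over both methods was 0.77 ± 0.70 (SE). NOG, a BMP antagonist, had 43, 32 and 0 node counts against 18, 0 and 0 lateral counts in manual embryos, and 0, 1 and 0 against 0, 0 and 16 in LCM embryos, so it does not mark the node in LCM embryo 3. GSC had 1 count in all 12 libraries together. FOXA2 was not analysed here.

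The first comparison asked which genes distinguish the node from the neighbouring tissue of the same embryo across both dissection methods. The genes with the smallest p values included TF, CA10, APLP2, CFC1, CAPSL and TBXT, each with a positive node minus lateral difference in 6 of 6 embryos. In LCM embryo 1 this rests on 2 counts against 0 for CA10 and 3 against 2 for CAPSL, too few to give a direction. In LCM embryo 2 CFC1 had 17 node counts against 0, of which 10 match the carried share described below. TF, which encodes the iron carrier transferrin, was higher by 2.36 ± 0.37 on the log2 scale, and CFC1, a co-receptor for Nodal ligands, by 9.17 ± 1.75. CA10, a carbonic anhydrase-related protein, was higher by 9.52 ± 1.53, with 1443, 2635, 1094, 2, 717 and 1580 node counts against 36, 0, 2, 0, 1 and 1 lateral counts. None of the 9491 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, so these are values and not calls. Without LCM embryo 1 CA10 (9.58) and CAPSL (7.08) passed, each with an adjusted p of 0.0243. At an unadjusted p under 0.05 there were 324 genes, 254 higher and 70 lower in the node, where uniform p values give 475. Other exchanges of node and lateral within embryos gave a median of 169 and at most 284, and other splits of the libraries at most 1058. The median log2 fold change of all genes was 0.171, and 0.06 with the carried share described below subtracted. DESeq2 size factors without that subtraction gave 0.096. The subtraction takes counts from a node library only, so it cannot tell how much of the lean to higher values comes from carried reads. Other tools called 239 genes (DESeq2) and 25 genes (limma voom), and edgeR without the filter on low counts called 36. The estimated biological coefficient of variation that remained with the embryo as a block was 122%.

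Among genes with the smallest p, CA10 and TF had an edgeR adjusted p of 0.163, APLP2 0.268, CFC1 and CAPSL 0.409, and HEP21, TBXT and KCNJ15 0.579. APLP2, an amyloid precursor-like protein, was higher in the node by 0.97 ± 0.17 (log2, SE), SALL1, a zinc finger transcription factor, by 0.90 ± 0.21, and CDH2, the gene of N-cadherin, by 1.19 ± 0.29. CAPSL was higher by 6.30 ± 1.26, HEP21 by 8.36 ± 1.80, GUCA2A by 4.33 ± 0.99 and CTNND2 by 1.76 ± 0.40. KCNJ15, a potassium channel, had 754, 612 and 163 node counts against 15, 0 and 0 lateral counts in manual embryos, and 1550, 3 and 3 against 0 in each LCM embryo. Of the genes with lower node values, CLDN1, the tight junction protein claudin-1, differed by -1.29 ± 0.32 and APOD, a lipid carrier, by -2.56 ± 0.67, each lower in 6 of 6 embryos. ROR1, a receptor tyrosine kinase of Wnt signalling, differed by -6.12 ± 1.64 and SEPT8, a septin, by -7.84 ± 2.14. ELMO1 differed by -3.85 ± 1.16 and KIF14, a mitotic kinesin, by -4.27 ± 1.60. The carried share described below accounts for the 9 counts of ROR1, 7 of the 8 of SEPT8 and the 30 of KIF14 in the node library of LCM embryo 2, and subtracting it moves these genes to -7.01, -8.72 and -5.35. OAT, CKB and IPO5 differed by -0.75 ± 0.23, -0.58 ± 0.20 and -0.42 ± 0.16. DESeq2 and limma voom together called 16 genes, an overlap looked up only after the values were seen, and 9 of them had a single direction in all 6 embryos. These 9 were CA10, CFC1, HEP21, CAPSL, KCNJ15, TF, APLP2, GUCA2A and SALL1, all with positive values. For CA10 and CAPSL in LCM embryo 1, KCNJ15 in LCM embryos 2 and 3, and GUCA2A in manual embryo 3 (1 node count against 0) both counts are at most 3, so the direction in those embryos is open.

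TBXT lies on chromosome 3 at 42233586 to 42241528, CFC1 on chromosome Z at 42279475 to 42284756, CHRD on chromosome 9 at 15406844 to 15413438, TF on chromosome 9 at 4096869 to 4107617 and CA10 on chromosome 18 at 5124020 to 5286048. These are whole-gene spans from the deposited table. The genome build is not given in the sources used here.

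**Figure D2:**
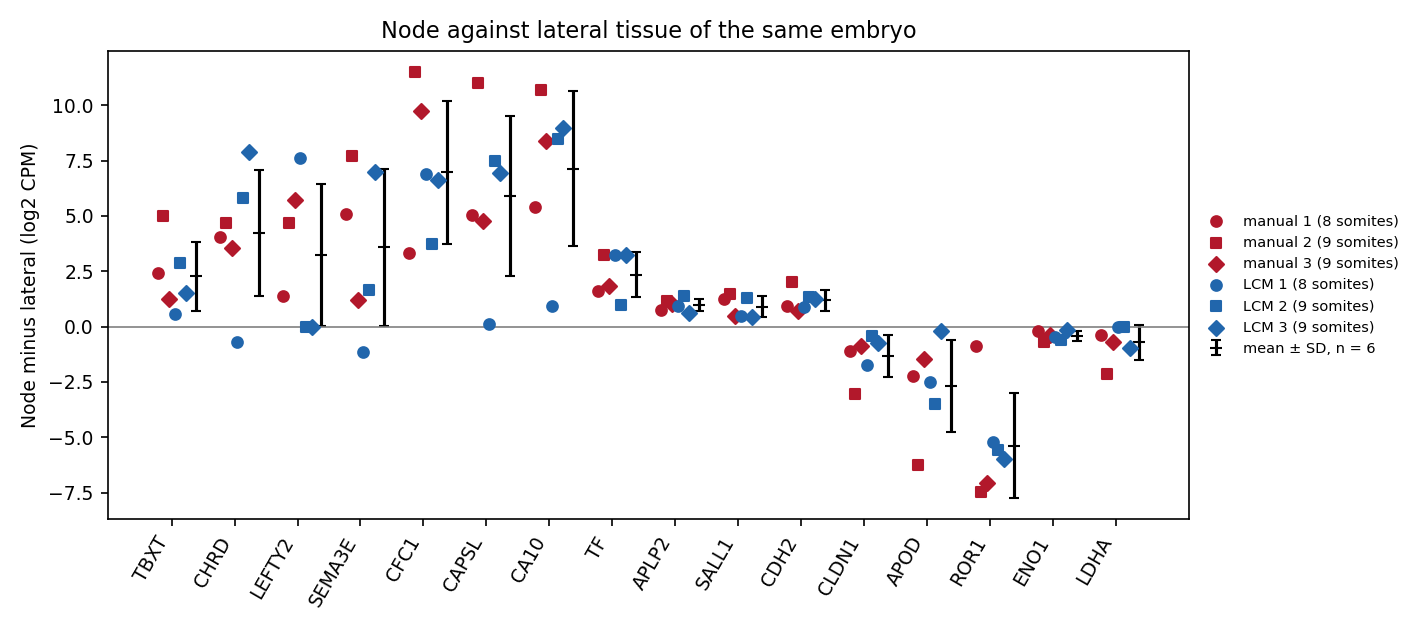
Node minus lateral difference in log2 CPM for 16 genes, with a point per embryo (red manual, blue LCM) and the mean ± SD over 6 embryos in black. TF, APLP2, SALL1 and CDH2 lie above 0 in all 6 embryos, and CLDN1 and APOD lie below 0 in all 6.

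Groups of genes were tested with lists chosen beforehand. The Organiser and notochord list was higher in the node than other genes (camera adjusted p = 0.00206). With an estimated correlation between its genes it did not pass (adjusted p = 0.432 with an estimated correlation). Of the 32 exchanges of node and lateral within embryos, the real one included, 2 gave this list a camera p as small. All 8 tested members had positive values, and 6 others in the table had too few counts to be tested. TBXT was at 2.2 ± 0.48, CHRD at 6.93 ± 2.88, and SEMA3E, a semaphorin, at 6.27 ± 2.79. LEFTY2, a Nodal antagonist, had 6, 40, 77, 418, 0 and 0 node counts against 1, 0, 0, 0, 0 and 0 lateral counts. No member passed over all genes, and TBXT passed when adjusted over the list alone (edgeR adjusted p = 0.00407). The mean over members was higher in the node of 6 of 6 embryos, by 1.96 ± 0.98 log2 CPM (SD, n = 6).

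The list of axial progenitor and stem zone genes was also higher in the node (camera adjusted p = 0.00206; adjusted p = 0.584 with an estimated correlation), with 17 of 22 members positive. FGF3 was at 1.44 ± 0.60 and RXRG at 7.00 ± 2.47, and the list shares TBXT and CHRD with the Organiser list. The Wnt response list was higher (camera adjusted p = 0.0425; adjusted p = 0.432 with an estimated correlation), with 19 of 24 members positive, 18 when scaled by DESeq2 size factors. Its leading members after TBXT were WIF1, a secreted Wnt inhibitor, at 6.33 ± 1.97 and LEF-1, a transcription factor of the pathway, at 1.06 ± 0.34. The retinoic acid list was higher (camera adjusted p = 0.0139; adjusted p = 0.432 with an estimated correlation), with 15 of 17 members positive. RXRG and RDH10, the latter at 6.02 ± 2.68, led it, and both enzymes of retinoic acid synthesis ALDH1A1 (2.44 ± 1.45) and ALDH1A2 (3.32 ± 2.04) had positive values. In each of the axial and Wnt lists 1 member, TBXT, passed when adjusted over the list alone, none did in the retinoic acid list, and 0 did over all genes by edgeR in any of them. At an unadjusted p under 0.05 these 3 lists held 5, 3 and 2 genes.

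2 lists were lower in the node. The heart list (camera adjusted p = 0.0373; adjusted p = 0.432 with an estimated correlation) had 6 of 8 members negative, with the sarcomere gene ACTN2 at -7.61 ± 2.45. Of the cytosolic ribosomal proteins (camera adjusted p = 0.0367; adjusted p = 0.784 with an estimated correlation) 50 of 69 were negative, 60 when scaled by DESeq2 size factors, with a median log2 fold change of only -0.04. The mean over the ribosomal members was higher in the node of 3 of 6 embryos (-0.06 ± 0.36 log2 CPM, SD, n = 6), and that over the heart list in 1 of 6 (-1.23 ± 1.40). No gene of either list passed over all genes or when adjusted over the list alone by edgeR, and each held 1 gene at an unadjusted p under 0.05. Calls for the Organiser and the axial progenitor lists held when each embryo was left out in turn. The heart call was lost without manual embryo 2 (adjusted p = 0.287), LCM embryo 2 (0.203) or LCM embryo 3 (0.245), and the ribosomal call without LCM embryo 1 (0.288). The Wnt call was lost without manual embryo 1 (0.0655), manual embryo 2 (0.109), LCM embryo 2 (0.0767) or LCM embryo 3 (0.0886), and the retinoic acid call without LCM embryo 3 (0.0629) and with the carried share in LCM embryo 2 subtracted (0.0539), the embryo with its largest difference (2.99 log2 CPM). An exact 2-sided sign-flip test on the embryo means reached its smallest possible p, 0.0313, for 6 lists (adjusted p = 0.162 over the 31 lists). These were the Organiser, Wnt, retinoic acid, presomitic mesoderm, and epithelial and mesenchymal lists, higher in 6 of 6 embryos, and the surface ectoderm list, lower in 6 of 6.

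**Figure D3:**
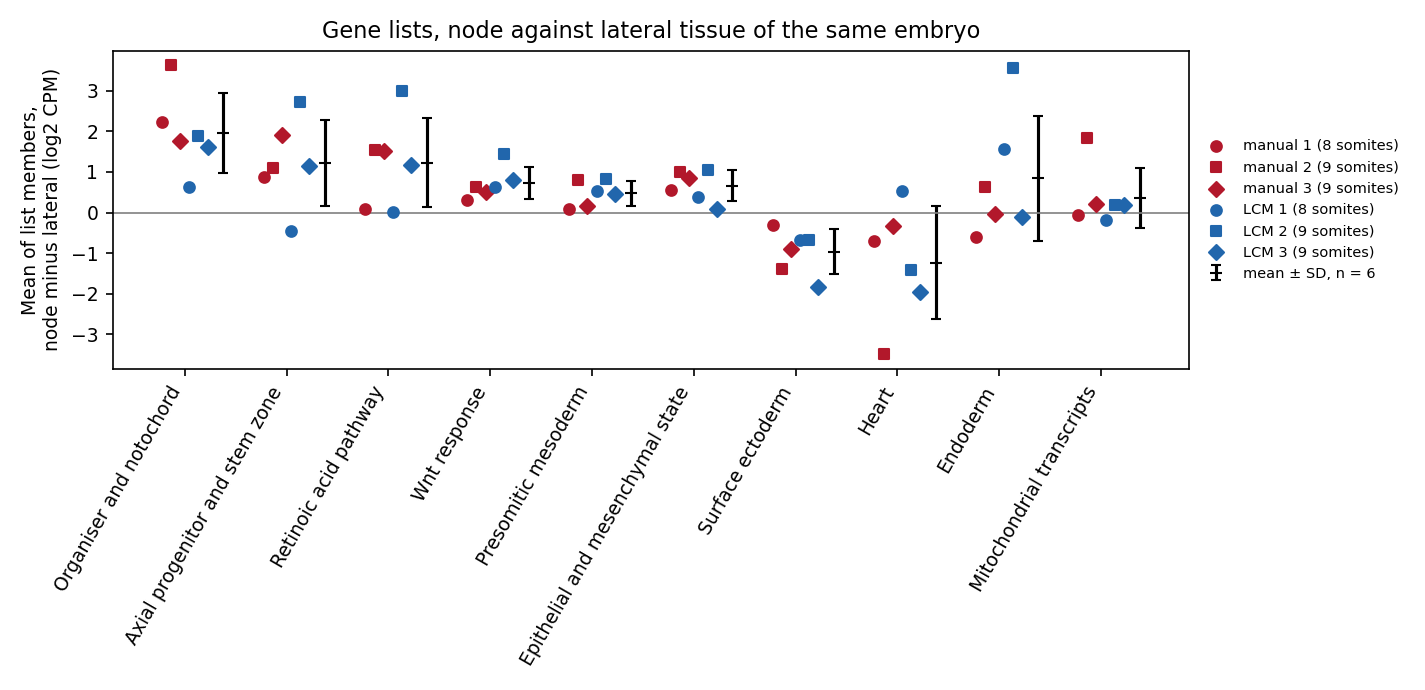
Mean of list members as the node minus lateral difference in log2 CPM for 10 gene lists, with a point per embryo and the mean ± SD over 6 embryos in black. The Organiser list lies above 0 in all 6 embryos, and the surface ectoderm list below 0 in all 6.

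Lists of the neighbouring tissues did not pass camera. The presomitic mesoderm list had 13 of 19 members positive (adjusted p = 0.332), with SNAI2 at 1.47 ± 0.41. The surface ectoderm list had 7 of 10 members negative (adjusted p = 0.0626), and passed with the carried share subtracted (0.0482), without manual embryo 3 (0.0479), without LCM embryo 1 (0.0471) and without the embryo block (0.0399). In the epithelial and mesenchymal list (adjusted p = 0.166) CDH2, CLDN1 and SNAI2 passed by edgeR when adjusted over the list alone, and none over all genes. In the neural plate list (adjusted p = 0.649) FABP7, a fatty acid binding protein of neural progenitors, was at -1.23 ± 0.27, PAX-7, a dorsal neural gene, at -8.57 ± 2.54 and CDH2 at 1.19 ± 0.29. These 3 passed when adjusted over the list alone and none over all genes. The endoderm list, markers of a tissue that a dissection could include, had 12 of 14 members positive (11 with DESeq2 size factors, adjusted p = 0.118), and TF and CLDN1 belong to it. Its mean was higher in the node of 3 of 6 embryos, and its camera adjusted p was 0.318 with the carried share subtracted. The neural crest list had 8 of 14 members positive (7 with DESeq2 size factors; adjusted p = 0.703), the intermediate and lateral plate mesoderm list 13 of 15 (0.213), the somite list 6 of 9 (0.50), the blood and endothelium list 7 of 10 (0.693), the notochord and floor plate matrix list 14 of 18 (0.232) and the Hedgehog list 5 of 7 (0.232), all by camera. In the neural plate and neural crest lists the median was positive while the mean and the camera direction were negative. In the blood and endothelium list the median and mean were positive and the camera direction was negative.

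Among the embryos dissected by hand, the Organiser and stem zone lists stood out most. The Organiser and notochord list was higher in the node (camera adjusted p = 5.44e-06; adjusted p = 0.457 with an estimated correlation), with 8 of 8 members positive and a median log2 fold change of 3.08. The axial progenitor list (camera adjusted p = 1.88e-04; adjusted p = 0.741 with an estimated correlation) had 16 of 22 members positive, the retinoic acid list (0.0219; adjusted p = 0.539 with an estimated correlation) 13 of 17 and the Wnt list (0.0461; adjusted p = 0.741 with an estimated correlation) 16 of 24. The mitochondrial transcripts were higher (0.00122; adjusted p = 0.741 with an estimated correlation), 10 of 12 positive, and the ribosomal proteins lower (0.0152; adjusted p = 0.820 with an estimated correlation), 58 of 69 negative. The mean difference of the ribosomal list was 0.04, -0.50 and -0.02 log2 CPM in manual embryos 1 to 3, and that of the mitochondrial list -0.07, 1.84 and 0.21, so embryo 2 carries both. In these libraries mitochondrial transcripts took 5.15% of the counts in the node of embryo 2 and between 1.36% and 2.58% in the other 5. TBXT was higher by 2.83 ± 0.67, TF by 2.21 ± 0.53, MYO3A, an unconventional myosin, by 8.30 ± 2.09, CA10 by 8.96 ± 2.11 and CAPSL by 6.38 ± 1.67. CLDN1 differed by -1.64 ± 0.46, APOD by -3.10 ± 0.99, CYTL1 by -5.80 ± 1.96, LDHA by -1.06 ± 0.36 and AKAP12 by -1.60 ± 0.59. In embryos 1 to 3 the log2 CPM differences were -1.10, -3.04 and -0.86 for CLDN1 and -2.25, -6.26 and -1.44 for APOD. For LDHA they were -0.37, -2.12 and -0.71. Embryo 2 thus had the largest difference in these genes, as it had for TBXT, TF, CA10 and CAPSL. By edgeR 0 of 9491 genes passed, the smallest adjusted p was 1, and 93 had an unadjusted p under 0.05, where uniform p values give 475. DESeq2 called 39 and limma voom 16. TBXT alone passed when adjusted over the list alone in the Organiser, axial and Wnt lists, and no member did in the other 3.

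In the laser-captured embryos 2 genes rose in the node by edgeR's quasi-likelihood test. GPR126, an adhesion G protein-coupled receptor on chromosome 3 at 52145374 to 52255811, rose by 8.42 ± 1.02 (adjusted p = 0.0171), with 2186, 358 and 1903 node counts against 4, 4 and 3 lateral counts. The unnamed gene ENSGALG00000026616 rose by 6.32 ± 0.86 (adjusted p = 0.0313), with 1144, 1997 and 1435 counts against 4, 28 and 73; it falls outside the naming rule and was named after its values were seen. The node library of LCM embryo 2 also held genes of the manual lateral library of embryo 1. There were 104 genes counted at 100 or more in that manual library and in no library outside its embryo other than this LCM library. Of these, 100 (96.2%) were counted in this LCM library, at a median of 3.45% of the manual count. Of the 358 counts of GPR126 in this library, 312 match that share. With the share subtracted, GPR126 stood at 7.60 ± 1.34 (adjusted p = 0.217) and ENSGALG00000026616 at 5.97 ± 0.83 (adjusted p = 0.107), and neither passed. Over 15 alternatives the adjusted p of GPR126 ran from 1.51e-16 to 1.00, and 10 passed. At an unadjusted p under 0.05 there were 495 genes, 369 higher and 126 lower, where uniform p values give 475. DESeq2 called 875 and limma voom 0. The median log2 fold change of all genes fell from 0.36 to 0.101 with the share subtracted. With DESeq2 size factors and no subtraction it was 0.189. Because the subtraction takes counts from a node library only, the part of carried reads in the lean to higher values stays open.

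**Figure D4:**
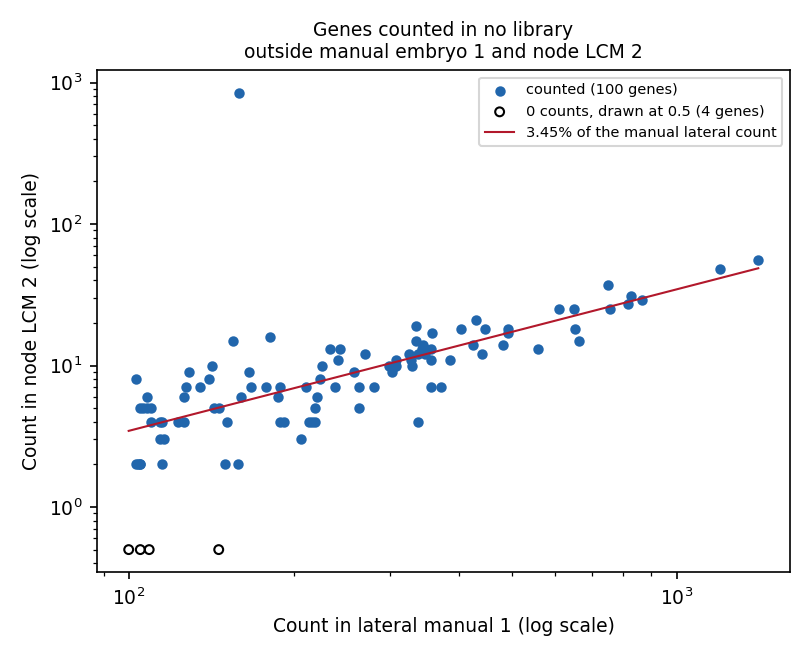
Counts in the LCM node library of embryo 2 against counts in the manual lateral library of embryo 1, both on log axes, for 104 genes. These were counted at 100 or more in the manual library and, outside its embryo, in no library other than the LCM one. The line marks 3.45% of the manual count; 4 genes at 0 are drawn at 0.5.

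Other genes with small p in the laser-captured embryos did not pass. TUBB6, a tubulin, was at 6.49 ± 1.15 and APOH, an apolipoprotein, at 6.36 ± 1.14, each with an edgeR adjusted p of 0.229. OBFC1, a telomere-associated factor, had 882, 1954 and 526 node counts against 3, 1 and 1, and GDPD5 3060, 77 and 2330 against 0, 1 and 0. KCTD17 was lower, with 2, 6 and 1 node counts against 1130, 936 and 610, and the small GTPase RND3 was at -2.62 ± 0.65. The carried share equals 1473 of the 2538 counts of TUBB6, 231 of the 452 of APOH, 52 of the 77 of GDPD5, 179 of the 203 of RND3 and all 6 of KCTD17 in the node library of LCM embryo 2. Subtracting it moves RND3 to -3.44 and KCTD17 from -8.24 to -9.80. APOH passed without LCM embryo 3 (8.05, adjusted p = 0.0234) and without manual embryo 2 (6.13, 0.0313), with a range of 3.54 to 8.05 over 15 alternatives, 4 of which passed (adjusted p from 3.41e-09 to 1.00). TUBB6 passed without manual embryo 2 (6.36, 0.00926), and 3 of its 15 alternatives passed. No list passed camera: the Organiser list had 5 of 8 members positive (adjusted p = 0.539), the axial list 16 of 22 (0.328), the Wnt list 19 of 24 (0.328), and the endoderm list 11 of 14 (0.242, the smallest). The median log2 fold change of all genes was 0.36, 0.19 with DESeq2 size factors and 0.101 with the carried share subtracted.

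The effects of the 2 methods were then set against each other. No gene differed between them by edgeR among 9491 tested. At an unadjusted p under 0.05 there were 246 genes, where uniform p values give 475. DESeq2 called 254 and limma voom 0. GPR126 was the nearest, with a larger node effect in LCM by 6.88 ± 1.22 (adjusted p = 0.415), followed by TUBB6 (6.36 ± 1.44), FOXM1, a cell cycle transcription factor (6.50 ± 1.56), and OBFC1 (9.17 ± 2.03). KCTD17 was at -9.35 ± 2.11, EDNRB, an endothelin receptor, at -11.56 ± 3.06 and DHX35 at -5.87 ± 1.61. No list differed by camera, and the smallest adjusted p was 0.0722 for mitochondrial transcripts, with 11 of 12 members negative. For the Organiser list the adjusted p of the difference was 0.360. With each method fitted on its own libraries, log2 fold changes of 6802 genes correlated weakly across genes, with a Spearman correlation of 0.09 and a Pearson correlation of 0.108, and genes are not independent replicates. The same sign was seen for 53.5% of genes, for 117 of 179 genes with an unadjusted p under 0.05 in manual embryos (65.4%), and for 141 of 211 in LCM embryos (66.8%). All 17 genes below that p in both methods had the same sign. Without manual embryo 2 the Spearman correlation was 0.028.

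Laser capture of fixed sections was also compared with live dissection, on counts summed over both libraries of each embryo. Genes of the G2/M phase were higher in LCM embryos (camera adjusted p = 1.97e-07; adjusted p = 0.365 with an estimated correlation), 33 of 42 of them, with a median log2 fold change of 0.94. CENPF, a kinetochore protein, was at 3.44 ± 0.58, the proliferation marker MKI67 at 4.85 ± 0.99 and the mitotic kinase PLK1 at 1.82 ± 0.38. Endoderm markers were lower (camera adjusted p = 0.00281; adjusted p = 0.467 with an estimated correlation), 11 of 12 of them, with a median of -2.33, and of -1.07 without manual embryo 1. The plasma protein genes TTR, RBP4 and APOA1 were at -5.08 ± 1.99, -5.06 ± 2.16 and -4.68 ± 2.21. The pluripotency list was higher (0.00281; adjusted p = 0.467 with an estimated correlation), 14 of 17, and so was the axial progenitor list (1.31e-04; adjusted p = 0.365 with an estimated correlation), 17 of 21. LIN28B, an RNA-binding protein of early cells, was at 1.45 ± 0.40, SALL4 at 1.48 ± 0.44, EVX1 at 3.42 ± 0.71 and FGF8 at 1.91 ± 0.60. Mitochondrial transcripts were higher (1.01e-04; adjusted p = 0.365 with an estimated correlation), 10 of 12, with MT-ND6 at 2.43 ± 0.39 and MT-ND1 at 1.66 ± 0.28. Of the HOX genes of groups 1 to 5 (0.0435; adjusted p = 0.365 with an estimated correlation) 10 of 10 were positive, 8 when scaled by DESeq2 size factors, with HOXA3 at 3.35 ± 1.04. When adjusted over the list alone 5 genes passed by edgeR in the G2/M list, 5 in the mitochondrial list, 4 in the pluripotency list, 1 in the axial list and 0 in the HOX and endoderm lists, and 0 over all genes.

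The HOX call was lost without manual embryo 1 (adjusted p = 0.140), manual embryo 2 (0.0651) or LCM embryo 3 (0.0561), and the pluripotency call without LCM embryo 2 (0.0757, with the median going from 1.45 to 0.82). No single gene passed by edgeR among 9113 tested, although 1210 had an unadjusted p under 0.05 (496 higher and 714 lower in LCM) where 456 are given by chance. DESeq2 called 720, limma voom 27, and edgeR 134 without manual embryo 1. TDH, threonine dehydrogenase, was nearest at -9.45 ± 1.01 (adjusted p = 0.0550), and 7 of its 15 alternatives passed (adjusted p from 1.40e-32 to 0.343). It had 2510, 2755 and 789 counts in manual node libraries and 115, 1388 and 2819 in manual lateral libraries, against 1, 8 and 7 and 1, 0 and 0 in the LCM libraries. The Notch ligand DLL1 was at 4.95 ± 0.69, NID2, a basement membrane protein, at 4.19 ± 0.57, ANKRD11 at 4.59 ± 0.69 and APOD at 3.69 ± 0.55 (each adjusted p = 0.134). HNRNPAB was at 2.32 ± 0.37 and SYNDIG1 at 3.22 ± 0.52. CBS, cystathionine beta-synthase, was at -4.27 ± 0.66, NECAP1 at -2.49 ± 0.37, ATP6V1A, a proton pump subunit, at -2.58 ± 0.48 and DEGS1 at -2.13 ± 0.38, with NUP93, MFAP3 and POLDIP3 between -1.77 and -1.88. In 2256 genes (24.8%) the 3 LCM and 3 manual embryos did not overlap, where chance gives 10%. Method and embryo cannot be told apart, because each embryo was dissected by a single method.

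**Figure D5:**
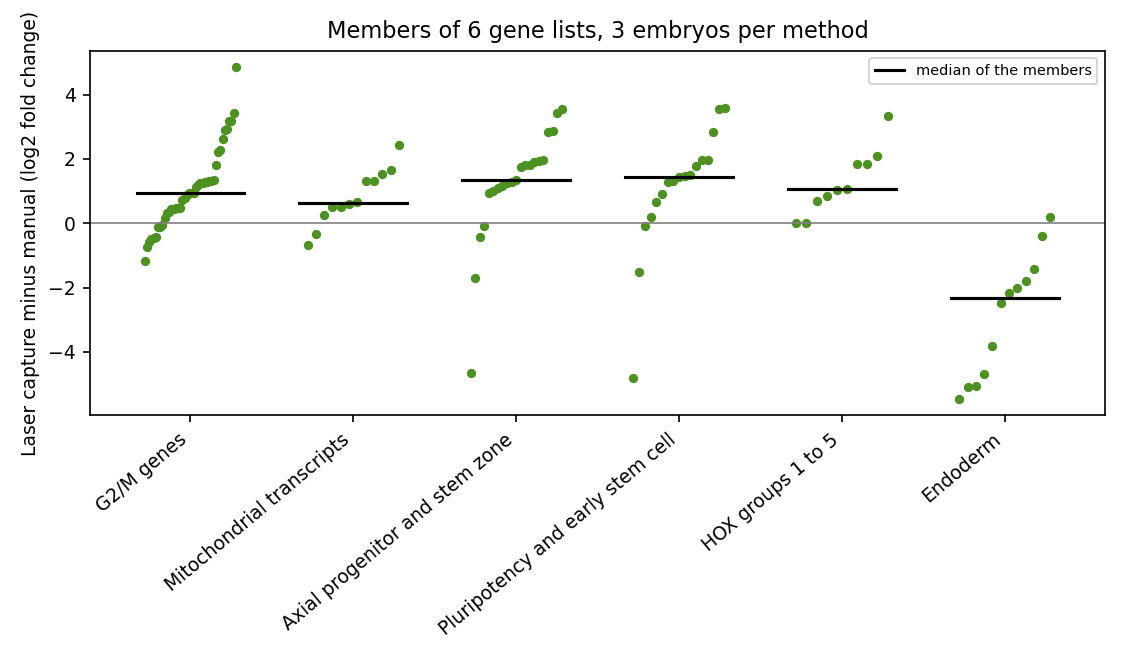
Log2 fold change of laser capture against manual dissection for every tested member of 6 gene lists, a point per gene sorted within its list, with the median as a bar (3 embryos per method). The G2/M median is 0.94 and the endoderm median -2.33.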

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

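The tests of carried reads were chosen only after the result was seen. Of 67 values per embryo or library examined for a single sample far from the others, 5 stood out, and chance alone picks about 1 in 20. No list moved in opposite directions in all embryos of the 2 methods, nor did the label checks CHRD and GNOT1. The other named genes of the comparison over both methods were chosen for a single sign in all embryos, so they could not. Of 9491 genes 205 did, where independent signs give 297. Genes with a single direction in all embryos numbered 173 to 274 under other exchanges of node and lateral, with a median of 228. The 205 is itself the count for the exchange of all LCM embryos, so it lies inside that range by construction.

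The W chromosome list stood apart in LCM embryo 2. Its node minus lateral difference was 4.61 log2 CPM there and -1.04 to 0.2 in the other 5 embryos, although both libraries of an embryo share its sex. The node library had 514 W counts and its lateral partner 60, and W genes share sequence with their Z copies. Manual embryo 1 had 11229 (node) and 12520 (lateral) W counts, and the remaining libraries had 35 to 360. Laser capture against manual dissection went from 0 to 134 called genes without that embryo. Whether its sex plays a part was not tested.

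The pattern behind the W counts of LCM embryo 2 is that the LCM node library of embryo 2 holds genes of the manual lateral library of embryo 1. Over the 104 genes concerned, its counts followed the manual lateral counts with a rank correlation of 0.804. The other 9 libraries gave at most 0.107, each over its own set of 108 to 129 genes. Each such set holds the same 104 genes, chosen to be at 0 in the library tested. A low correlation there was thus largely set in advance. This comparison cannot decide on a more complete recovery of the LCM library's own transcripts, which stays open. Reads of the manual node library of that embryo are argued against as the whole source by its own dominant genes, which appear at 0.86% of their counts against 3.49% for genes dominant in the lateral library, but these node genes stand at 7.49% of the lateral counts, so a smaller part from it stays open. A candidate source is reads of the manual lateral library, which would make up about 4.86% of the total. Of the 104 genes 96.2% were counted. In the sets of the other libraries at most 19.4% were counted. That share is no control, because 104 genes of each set were chosen to be at 0 in that library. Subtracting this share lowers the W counts to 91, the step at which such reads could have moved stays open, and no biological explanation was tested.

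Mitochondrial transcripts took 2.714% of counts in the same LCM node library and 3.077% to 3.203% in the other 5 LCM libraries, and 2.75% after the subtraction. In the manual node library of embryo 2 they took 5.151%, and 1.363% to 2.578% in the other 5 manual libraries. The mean difference of the mitochondrial list was 1.84 log2 CPM in manual embryo 2 and -0.19 to 0.21 in the other embryos. For ROR1 the difference was -0.88 log2 CPM in manual embryo 1 and -7.48 to -5.23 in the other 5.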

How the results depend on the processing

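Subtraction of the carried share, the restriction to genes counted in all 12 libraries, and the leave-outs for the agreement were chosen after seeing the data. Without the filter on low counts edgeR called 36 genes for node against lateral in both methods, 7 in manual embryos, 33 in LCM embryos, 5 for the difference of the methods and 19 for laser capture against manual dissection. DESeq2 called 239, 39, 875, 254 and 720. Limma voom called 25, 16, 0, 0 and 27. For both methods together the mean of the method effects called 1 gene and embryos of 9 somites 7. For LCM embryos the 2 calls became 0 with a minimum CPM of 5, with genes counted in all 12 libraries and with the carried share subtracted, and the fit on their own 6 libraries called 2 other genes, both lower, with 0 shared. For laser capture against manual dissection 1 gene was called with DESeq2 size factors, 1 with a minimum CPM of 5, 2 with the carried share subtracted and 139 with 12 libraries and a population term. That last fit counts both libraries of an embryo as replicates. The fit without the embryo block, that is without the pairing, left 1 call in LCM embryos and 0 in the other comparisons it applies to, and 7 lists were called without it. Genes at an unadjusted p under 0.05 went from 495 to 823 in LCM embryos and from 246 to 458 for the difference of the methods.

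Leaving out each embryo in turn gave 0 to 4 genes for both methods (4 without LCM embryo 1, 2 without manual embryo 1), 0 to 1 for manual embryos (1 without manual embryo 1), 1 to 9 for LCM embryos (9 without LCM embryo 3, 7 without manual embryo 2, 4 without LCM embryo 1, 1 without manual embryo 3 or LCM embryo 2), 0 to 0 for the difference of the methods and 0 to 134 for laser capture against manual dissection (134 without manual embryo 1). Where a method kept 2 embryos, the spread was shared with the other. Of the 6 list calls 0 held with an estimated correlation and 0 with fry, leave-outs gave 3 to 10 (3 without LCM embryo 3, 10 without manual embryo 3), and subtraction of the carried share kept 5 of them, with the retinoic acid list at an adjusted p of 0.0539 (0.0112 to 0.432 over its alternatives). With that share subtracted GPR126 went from 8.42 ± 1.02 to 7.60 ± 1.34, a smaller fold with a larger error, and ENSGALG00000026616 from 6.32 ± 0.86 to 5.97 ± 0.83. The Spearman correlation between the methods was 0.028 without manual embryo 2 and up to 0.098. Other settings, the normalized values with limma included, left their count of calls within 1.5 times. For the 73 gene results, 1025 of 1183 alternatives kept direction and side of the threshold, 153 passed where the reported one had not, and 5 failed where it had. No named gene reversed its direction. Nearly all were chosen from the same libraries for a small p and a single sign, so this outcome was largely set by that choice. For the 31 lists these were 266, 10 and 22 of 309, and 11 reversed, all with an adjusted p above 0.05 in both settings. With fry the neural plate, neural crest, blood and endothelium, and HOX 1 to 5 lists turned positive (each adjusted p = 0.860), as did G2/M (0.553). The mitochondrial list turned negative without manual embryo 2 (0.287), and the W chromosome list without LCM embryo 2 (0.774) and with the carried share subtracted (0.986). The neural plate list turned positive without LCM embryo 1 (0.857), HOX 1 to 5 without LCM embryo 2 (0.640) and blood and endothelium without LCM embryo 3 (0.887). On leaving out embryos the adjusted p ran from 0.3272 to 0.9262 for neural plate, 0.5798 to 0.9305 for blood and endothelium, 0.275 to 0.9676 for HOX 1 to 5, 0.06405 to 0.3982 for mitochondrial and 0.1682 to 0.7744 for W chromosome genes. Over the alternatives the median of all genes ran from -0.009 (without LCM embryo 2) to 0.253 (without LCM embryo 3) for both methods, against 0.171 as reported. In LCM embryos it ran from 0 to 0.858 on leaving out those embryos, against 0.36. For the difference of the methods it ran from 0.037 (genes in all 12 libraries) to 0.808 (without LCM embryo 3), against 0.355. For laser capture against manual dissection it ran from -0.2 (voom) to 0.128 (without manual embryo 1), against 0.062, and in manual embryos from -0.055 to 0.019. The cause was not tested for any other changed count. Genes at 0 in single libraries, 4658 per LCM library on average, limit what this depth can show.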

Other observations

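Tests of direction in genes called by DESeq2, of lists over genes counted in all 12 libraries, and with the carried share subtracted, were chosen only after results were seen.

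Lists beyond those above did not pass camera for node against lateral tissue in both methods together, although single members stood out. The BMP, TGF-beta and Nodal list (15 of 26 members positive, camera adjusted p = 0.239) had 6 members at an unadjusted p under 0.05 and the smallest p of the 31 lists by fry for change in either direction (adjusted p = 6.92e-04). In it CFC1 and FSTL1, a follistatin-like secreted protein at 2.65 ± 0.67, passed by edgeR when adjusted over the list alone and 0 over all genes. FSTL1 was higher in the node of 6 of 6 embryos. In the glycolysis list (10 of 19 negative, 11 with DESeq2 size factors; 0.155) the abundant enzymes ENO1, GAPDH, PGK1 and LDHA were at -0.42 ± 0.12, -0.40 ± 0.13, -0.36 ± 0.12 and -0.69 ± 0.26, and 0 passed over the list alone. Motile cilia genes (14 of 25 positive; 0.396) held CAPSL, which alone passed over the list, and this list passed fry for change in either direction (adjusted p = 0.0025). SALL1 alone passed in the pluripotency list (11 of 19 positive; 0.589). By camera FGF response (12 of 20; 0.232), Notch (11 of 15; 0.649), HOX groups 1 to 5 (6 of 10; 0.693), HOX groups 6 to 13 (4 of 9; 0.499), immediate early and heat shock (13 of 21; 0.649), mitochondrial transcripts (11 of 12; 0.205) and W chromosome genes (6 of 7; 0.649) did not pass. Nor did genes of S phase (26 of 39 negative; 0.117), G2/M (20 of 42 negative, 23 with DESeq2 size factors; 0.649) and nuclear oxidative phosphorylation (38 of 64 negative; 0.232). The S phase, glycolysis and oxidative phosphorylation lists passed as lower without manual embryo 1 (each 0.0499) or manual embryo 3 (each 0.0479). The median and the mean had opposite signs in the glycolysis, HOX 6 to 13 and oxidative phosphorylation lists. For HOX 1 to 5 and G2/M both were positive and the camera direction was negative, and the G2/M median was negative with DESeq2 size factors (-0.05).

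A direction shared by all embryos was more frequent than in exchanged libraries. In 318 of 9491 genes node and lateral differed the same way in 6 of 6 embryos, 224 higher and 94 lower in the node, where independent signs give 297, and some rest on counts at or under 3 in an embryo. Over the 32 exchanges of node and lateral within embryos this was the highest count, and the highest other was 274. With a mean difference above 1 the counts were 229 and 196. The Spearman correlation of mean differences between the methods was 0.083. Regardless of sign, 4 of the 32 exchanges were as large, the real one included. The other exchanges ran from -0.103 to 0.103.

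Between laser capture and manual dissection, single members of other lists stood out. GLI3, a transcription factor of Hedgehog signalling, was at 2.28 ± 0.45, DLL1 at 4.95 ± 0.69 and SNAI1, a repressor of epithelial genes, at -4.06 ± 0.81. Each passed by edgeR over its list alone and not over all genes. In the retinoic acid list (9 of 17 negative, camera adjusted p = 0.326) ALDH1A1 was at -5.38 ± 1.81 and CYP26A1, which degrades retinoic acid, at 2.83 ± 1.05.

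The lists that differed between laser capture and manual dissection may reflect gene dropout, carried reads or the embryos themselves. Over genes counted in all 12 libraries 5 of the 6 lists were called in the same direction, which argues against random misses as the whole cause, and HOX groups 1 to 5 did not pass (adjusted p = 0.0840; 0.0106 to 0.365 over its alternatives, the highest with an estimated correlation). With the carried share subtracted 6 of 6 were called, so the calls do not depend on it. Reads carried from a manual into an LCM library would make the methods more alike, so this test cannot decide on carry-over as a cause. Other differences between the embryos cannot be told apart from the method, because 0 embryos were dissected by both. The biological difference between embryos and the handling of fixed tissue both stay open.

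DESeq2 called 239 genes for node against lateral in both methods where edgeR called 0 (324 at an unadjusted p under 0.05). Of the called genes 70.7% had a library at 0 counts, against 48.3% of all tested genes and 63.6% to 90.2% of those called under exchange, and random misses cannot be told apart here, because genes absent from a tissue also have libraries at 0. A tool that calls too many genes cannot be told apart either: only 1 of 32 exchanges within embryos, the real one, called as many, but the highest other called 228, within the spread of 38.8 over exchanges, and in simulated counts 163 DESeq2 calls were false. A difference of tissue predicts more genes with a single direction in 6 of 6 embryos than under exchange. That share was 41.4%, with a median of 31.8%, a spread of 4.7 points and a highest other of 42% under exchange, so it cannot be told apart, although the 99 such genes lay above the highest other count of 61, and the tissue difference stays open.

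For both methods together the real split called 0 genes in edgeR and the highest other of 100 splits 4. With a real count of 0 every split is as large by construction, so chance is not excluded and the count of splits tells nothing more. At an unadjusted p under 0.05 it had 324 genes, the highest other split 1058, and the highest other exchange within embryos 284. For manual embryos, LCM embryos, the difference and laser capture against manual dissection there are 10 splits each, too few for a share under 0.05. The real counts were 0, 2, 0 and 0 and the highest others 1, 30, 0 and 0. At an unadjusted p under 0.05 the real counts were 93, 495, 246 and 1210 and the highest others 251, 1110, 267 and 400. Most of the splits within a method part fewer pairs than the real one. In the 4 exchanges of LCM node and lateral libraries within embryos the highest other called 0 genes, with 438 at an unadjusted p under 0.05. Why an LCM split gave 30 calls was not tested. For the list tests chance cannot be excluded, with 6 lists called, a highest other of 6 and 2 of 32 exchanges as large. For the Organiser list alone the camera p was 1.17e-04 and the smallest under another exchange 4.41e-06. For the lists between laser capture and manual dissection 10 splits are too few, with 6 lists called and a highest other of 4.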
